A study of Mus musculus with 4 samples.

How the data were processed

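The data are 1 table of expression values for 4 arrays of sorted mouse ILC3s, with 1 array for each genotype. Per the labels' protocols, ILC3s were sorted by flow cytometry, total RNA was extracted with Trizol and labelled cDNA was hybridised. Per the submitters' processing notes, the deposited values were made with Affymetrix Power Tools and RMA, a method that corrects background, normalizes arrays by quantiles and summarises the probes of each transcript. Versions and settings are not given in the sources used here. The deposited values are on a log2 scale with 2 decimals, as the range of 2.13 to 19.93 and the shape of the distributions show. The highest value is shared by 21 rows in the circZbtb20 wild type, 3 in the circZbtb20 knockout, 25 in the Nr4a1 wild type and 18 in the Nr4a1 knockout. Such values were treated as a ceiling, so that a difference from 1 of them is a bound, and a pair at the ceiling gives no difference. The reason for the ceiling is not given in the sources used here. Whether the deposited values keep the usual scale of RMA is therefore not known. Log2 differences and fold sizes describe the deposited values and need not equal ratios of RNA abundance. Quantile normalization forces similar distributions on all arrays. A change of total RNA per cell therefore cannot be seen in these values, and a large change in many genes can shift others. The deposited distributions were still not identical. The 95th percentile ranged from 11.38 in the circZbtb20 wild type to 11.89 in its knockout, and the rows at the ceiling differed in number as given above.

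The series design text names the protocol of an Affymetrix mouse gene array, while the identifiers of the rows are listed for another Affymetrix mouse platform in the probe table used here. The rows were named through that probe table. Of 22205 rows, 19571 had 1 gene symbol, 0 had several and 2634 had none. All 19571 symbols were found in a RefSeq gene table, which was used for names only. The genome build behind the rows is not given in the sources used here, so no coordinates are printed. For the 55 genes with several rows, the row with the highest mean over the 4 arrays was used, which left 19504 genes. Of the 12 such genes that the rule of size called in the circZbtb20 comparison, 10 had the same sign in the next brightest row, and of 17 in the Nr4a1 comparison, 13 did. Across the 55 genes, the differences of the 2 brightest rows correlated at Pearson r = 0.615 in the circZbtb20 comparison. That correlation was 0.935 in the Nr4a1 comparison and 0.756 between the wild types. Some genes of the fixed lists and of the fixed set for naming have no row here and were not analysed here. Detection calls were not used here. Values near or under the array medians, between 4.34 and 4.51, depend on background, so differences between low values are poorly measured.

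The samples were grouped by title and genotype label. Each knockout was set against the wild type that its title pairs with it, and the wild types were set against each other as a background. With 1 array per genotype there is no replicate error, and the main comparisons have no p-value. The only p-values come from a limma fit, given as an alternative, whose error rests on the difference between the wild types. Genes were counted by a rule of size, an absolute log2 difference of at least 1 with the higher value at or above that array's median over all rows. A stricter count also asked for a 2-fold difference in the same direction against the other wild type. The overlap of the comparisons was set beside that of independent lists of the same sizes, counted per direction among genes past the filter in both. For each gene list with at least 3 measured genes the median log2 difference was given, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. A percentile describes these arrays and not the conditions. For the NR4A family, random triples matched on wild-type level were also drawn.

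Before the data were examined, 41 gene lists, the rule of size, the processing alternatives and the rule for naming genes were fixed. Of these lists 37 had at least 3 measured genes. Genes named in every comparison were the NR4A family, Notch1, Notch2, Il22, Il17a, Il7r, Alkbh5 and Bcl2, with others not analysed here. Each comparison also named the 10 highest and 10 lowest differences among genes past the rule against both wild types, without predicted genes, small RNAs, olfactory receptors and antigen receptor segments. From each list up to 4 members with the greatest absolute difference past the rule were named, and for the overlap up to 10 genes. A second list of acinar genes was written after the result of the pancreas list was seen but before the values of its own genes were seen, as was a second list of T cell genes after the first T cell list. A list of thymocyte-stage genes was written after values were seen.

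The alternatives were quantile and cyclic loess normalization of the 4 arrays, the other wild type or the mean of both as reference, no filter or a filter at the 75th percentile, sizes of 1.5-fold and 3-fold, and the mean of the rows of a gene. A further alternative was limma with both wild types as 1 group, which has 1 residual degree of freedom before moderation and a prior of 2.54, with Benjamini-Hochberg adjustment. Counts without genes at the ceiling and counts over all rows were added after the data were seen.

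The rules were tested on simulated data for 19504 genes. In a simulated circZbtb20 comparison the rule of size recovered 60.0% of genes with a log2 change of 1, 88.0% with 2 and 100% with 4 or 8. It called 7.05% of all unchanged genes, those under the filter included. The simulated noise was drawn from the difference between the wild types. That share is therefore neither an independent rate of false calls nor comparable with the shares of genes past the filter in the Results. The limma fit recovered 0 of 200 changed genes in 1 simulation. With 4000 changed genes it recovered 4.6%, 49.3%, 76.3% and 92.7% of those with log2 changes of 1, 2, 4 and 8, with 45 calls among unchanged genes. Of 100 random lists of unchanged genes, 6 lay outside the central 95%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.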

Results

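Gene expression was measured with 1 Affymetrix array for each of 4 samples of mouse group 3 innate lymphoid cells (ILC3s), lymphocytes without rearranged antigen receptors that make IL-22 and IL-17 at barrier surfaces. The cells were sorted as negative for lineage markers, high for CD90 and low for CD45. The labels used here name neither the lineage markers nor the tissue. One sample came from mice without circZbtb20, a circular RNA made from exons of the Zbtb20 gene, and another from mice without Nr4a1, an orphan nuclear receptor induced early after stimulation of lymphocytes. Each knockout has a wild type paired with it by title. Each genotype has 1 array, so the values below have no replicate error and the number of arrays limits the precision. The differences and counts rest on no test, and the only fit with p-values treated both wild types as 1 group. Differences are given as log2 differences, knockout minus its own wild type. A gene counts here as higher or lower when it differed at least 2-fold and the higher of its values reached that array's median. The difference between the wild types, measured the same way, serves as the background. The array medians were 4.48 for the circZbtb20 wild type, 4.38 for the circZbtb20 knockout, 4.51 for the Nr4a1 wild type and 4.34 for the Nr4a1 knockout. The highest value of the table, 19.93, is a ceiling, so a difference from it is only a bound. Fold sizes refer to the deposited values, whose relation to RNA abundance was not tested.

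The targeted genes were read first, as a check on the labels. Nr4a1 stood at 11.63 in the Nr4a1 knockout, against 18.11 in its wild type, 15.98 in the circZbtb20 knockout and 19.93 in the circZbtb20 wild type. It was therefore lowest in the array labelled as its knockout, by -6.48 against the paired wild type. On the same array Nr4a2 and Nr4a3, which were not targeted, differed by -7.81 and -7.36. The low Nr4a1 value therefore does not by itself support the label. The signal that remained equalled the 95th percentile of that array, 11.63. Which part of Nr4a1 was deleted, and where the probes lie, is not given in the sources used here, so a signal that remains neither supports nor opposes the label. No value is given for circZbtb20 itself, because a row that measures the linear transcript of a host gene does not measure its circular RNA. The host gene was not analysed here.

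The first comparison asked which genes differ between ILC3s with and without circZbtb20. The study was about this circular RNA in relation to Nr4a1, Notch2 and Alkbh5, an enzyme that removes the m6A mark from RNA. All 3 genes of the NR4A family were lower in the circZbtb20 knockout. Nr4a1 differed by -3.95 or more in size and Nr4a3 by -3.73 or more in size, since both were at the ceiling in the paired wild type, and Nr4a2 differed by -1.88. The family's median of -3.73 is thus itself a bound. As printed it lay at percentile 0.68 of random gene triples matched on mean expression and at 2.41 of triples matched on wild-type level, and these are not exact ranks. The median between the wild types was -0.03. Nr4a1 itself differed between the wild types, and against the other wild type its difference was -2.13. Notch2, at 9.73 against 10.63, differed by -0.90 and did not reach the 2-fold size, nor did Alkbh5, at 0.83. Notch1, low on all arrays, was higher by 1.59. The survival gene Bcl2 was lower by -1.53, and by -2.59 against the other wild type.

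Of the 10 highest genes of the circZbtb20 knockout, 3 encode cytokines. Il17a was at 15.79 in the circZbtb20 knockout and at 5.10 in its wild type, a difference of 10.69, and Il17f was higher by 7.71. Ifng, the type 1 cytokine, was at 18.25 against 8.37, a difference of 9.88, and of 8.09 against the other wild type. Il22 was at 18.34 against the ceiling, lower by -1.59 or more in size. Iltifb, a near-identical copy of Il22 named here after its values were seen, was at 19.90 against the ceiling, and probes may not separate the pair. Among 16 cytokines and effectors of ILC3s, 5 were higher and 5 lower, with a median of 0.11, and of -0.14 against the other wild type. Ltb, a subunit of lymphotoxin, was higher by 5.09, and Il10 was lower by -2.77.

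ILC3 identity genes did not move in 1 direction in the circZbtb20 knockout. For scale, the rule of size called 46.7% of all genes past the filter on low values in this comparison. A call by itself therefore sets no gene of these lists apart. Of 20 transcription factors 5 were higher and 6 lower, with a median of 0.42, and of -0.48 against the other wild type. Batf was higher by 4.78 and Nfil3 by 3.12. Of 30 surface receptors 11 were higher and 10 lower, with a median of 0.59. Vipr2, a receptor for vasoactive intestinal peptide, was higher by 4.99, Il7r, the IL-7 receptor, was higher by 1.42, and Pdcd1, which encodes PD-1, was lower by -4.90. The 12 markers of lymphoid tissue inducer-like ILC3s had a median of 0.16, and of 1.10 against the other wild type, with Ccr6 higher by 2.81. The 15 markers of ILC3s that bear natural cytotoxicity receptors had a median of 0.57, and of 0.14 against the other wild type, with Il12rb2 lower by -5.94 and Ccl3 by -7.62. Of 9 Notch receptors and ligands 2 were higher and 1 lower, with a median of -0.06. Of 28 Notch signalling components and targets 6 were higher and 10 lower. Il2ra was lower by -5.04, Dtx1 by -3.71 and Hes1 by -2.70, while Numb was higher by 3.20. Against the other wild type the median of the receptors and ligands was -0.11 and that of the components -0.26, and Batf was higher by 2.84, Vipr2 by 2.51 and Numb by 2.06.

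Of 18 NK cell and ILC1 markers 10 were lower in the circZbtb20 knockout and 1, Ifng, was higher. Their median of -1.33 lay at percentile 0.03 of matched random lists, with Gzma lower by -6.76, Ccl5 by -3.91 and Nkg7 by -3.79. Of 14 ILC2 markers 6 were lower and 1 higher, with a median of -0.90, under the 2-fold size, at percentile 0.25, and of -1.39 against the other wild type. Il17rb was lower by -9.21, Il5 by -8.16 and Il4 by -4.67. Of 33 chemokines and chemokine receptors 12 were lower and 5 higher, with a median of -0.50 at percentile 0.62. Ccr8 was lower by -6.93 and Cxcl10 by -4.23. Of 19 macrophage markers 7 were lower and 3 higher, with a median of -0.65 at percentile 1.23. Fcer1g was lower by -3.12 and C1qb by -3.05, while Fcgr3 was higher by 2.74. Against the other wild type that median was -1.41 and C1qb was lower by -5.27. The medians of these 4 lists between the wild types were -0.11, 0.26, 0.53 and 0.65, in the same order.

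Genes of mitochondrial respiration were higher in the circZbtb20 knockout, on its single array. Of 82 oxidative phosphorylation subunits 48 were higher and 8 lower, with a median of 1.29 at percentile 100, against -0.12 between the wild types. Ndufa2, of complex I, was higher by 7.09, Uqcr10, of complex III, by 6.58 and Cox7a2, of complex IV, by 5.26. Pmpcb, a mitochondrial processing peptidase, was higher by 6.76. Other abundant housekeeping genes differed in both directions on this array. Of 75 genes caught by the ribosomal protein pattern 19 were higher and 23 lower, with a median of 0.01, or -0.36 against the other wild type, where the wild types gave 4 higher and 0 lower. Rpl39 was lower by -7.05, Rpl10a by -5.64 and Rpl17 by -5.30, and the pattern also caught Rps6kb2, a kinase gene, at -6.75. In the Nr4a1 comparison the same pattern gave 9 higher and 7 lower. Tmsb4x, a thymosin that binds actin, was lower by -9.80, at 10.05 against 19.85 to 19.88 on the other arrays. Whether the quality of this array or its RNA contributed to such shifts was not tested.

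Further lists in the circZbtb20 knockout had medians near 0 against its own wild type, with members on both sides, but not all stayed there against the other wild type. The 33 immediate-early genes, which respond quickly to stimulation, had a median of -0.18, with Egr1 lower by -5.86 and Zfp36 by -5.56. Against the other wild type Zfp36 was lower by -7.50. The 18 heat shock genes had a median of 0.29, with Hspa5 lower by -3.23 and Dnajb1 higher by 5.02, but by only 1.09 against the other wild type. Glycolysis genes had a median of 0.39, with Slc2a1 higher by 3.34 and Ldha lower by -3.96, and fatty acid oxidation genes a median of 0.36. The m6A writers, erasers and readers had a median of -0.32, with Ythdf3 higher by 2.05 and the eraser Fto by 1.70. Apoptosis regulators had a median of 0.00, with Mcl1 lower by -3.94, or -5.66 against the other wild type, and Cflar higher by 2.68. Cell cycle genes had a median of -0.08, interferon-stimulated genes of 0.12 and MHC class II genes of -0.27. Against the other wild type the medians were -1.27 for immediate-early genes, -0.91 for MHC class II, -0.77 for heat shock, 0.54 for interferon-stimulated genes and -0.26 for apoptosis. The glycolysis median moved to -0.09. Those of fatty acid oxidation, at 0.09, and the cell cycle, at -0.25, shifted by less than 1 SD of their matched random lists. H2-Ab1 was lower by -2.12, and by -3.91 against the other wild type. H2-Eb1 was higher by 2.17 against its own wild type but at -0.34 against the other wild type.

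Pancreatic enzyme genes were far lower in the circZbtb20 knockout than in its wild type. Amylase Amy2a4 was at 18.98 in the wild type and at 9.36 in the knockout, a difference of -9.62. Ctrb1, a chymotrypsinogen, was lower by -10.89, Cpb1 by -9.20 and Cpa1 by -8.65, both carboxypeptidases. Of 14 hepatocyte and pancreas markers 10 were lower and 0 higher, with a median of -4.59. The wild types themselves differed on this list, by a median of -2.18, lower in the Nr4a1 wild type. Against that wild type the median was -2.03, with Amy2a4 at -5.88, Cpb1 at -4.69 and Cpa1 at -4.92. The amylase genes are near-identical copies, so their values are not separate measurements. The 10 highest genes of the rule for naming also held Gdpd3 at 13.29, Rbx1 at 6.75, Stip1 at 6.71 and the Y-linked gene Uty at 8.33. Kdm5d, also Y-linked, was higher by 4.70, so Y-linked signal differed within this pair. Against the other wild type Uty was at 1.02 and Kdm5d at 1.43. Its 10 lowest also held Amy2a2 at -9.84, Amy2a5 at -9.46, Tff2 at -9.12 and Rmc1 at -8.96. Against the other wild type Amy2a2 was at -6.41, Amy2a5 at -5.93 and Tff2 at -2.39.

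By the rule of size 3035 genes were higher and 2157 lower in the circZbtb20 knockout, 46.7% of the 11122 genes past the filter on low values. The same rule called 15.2% of genes between the wild types. Against both wild types, 2380 were higher and 1576 lower. No test stands behind these counts. With both wild types treated as 1 group, limma called 0 genes at its adjusted p, with 4681 genes at an unadjusted p under 0.05.

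**Figure D1:**
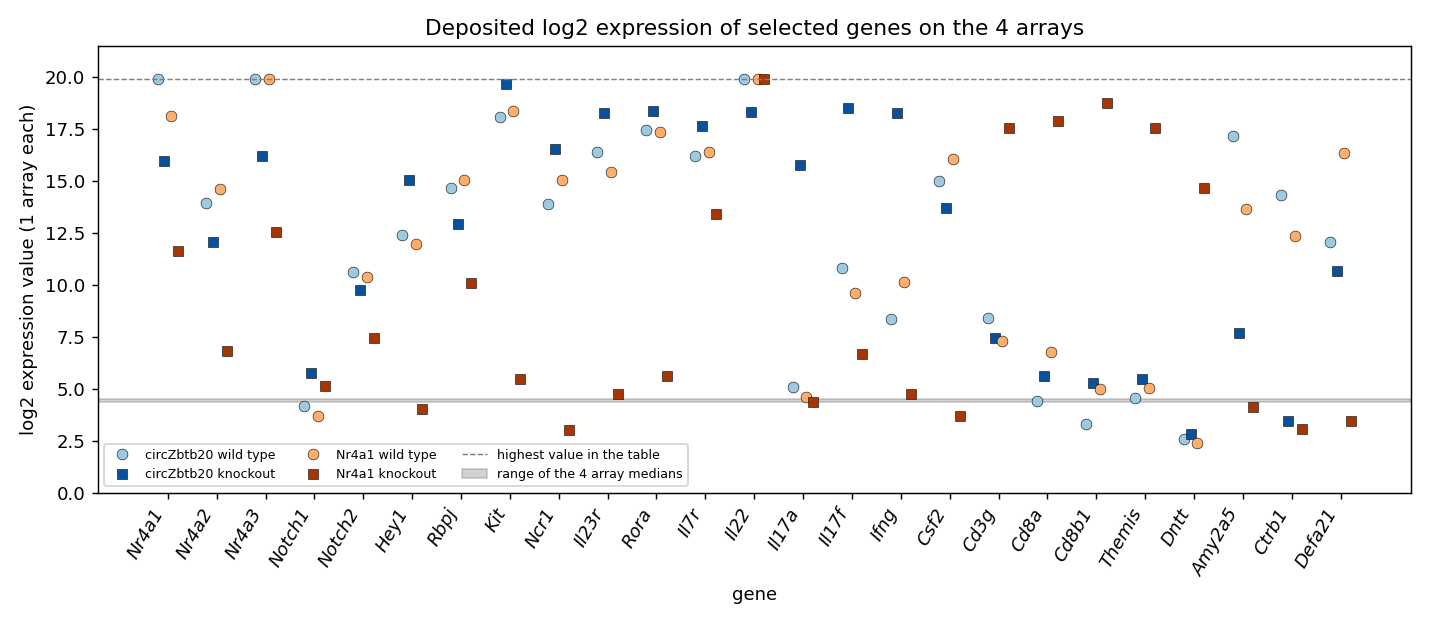
Log2 expression (vertical axis) of 25 genes (horizontal axis) on the 4 arrays, circles for wild types and squares for knockouts, with 1 point per array and no error bars; the dashed line is the highest value in the table and the grey band the range of array medians. Nr4a1 lies at 11.63 in the Nr4a1 knockout, Cd8b1 at 18.73 there and at or below 5.27 elsewhere, and Il17a at 15.79 in the circZbtb20 knockout alone.

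The next comparison asked which genes differ between the arrays labelled as ILC3s with and without Nr4a1. T cell genes were higher and ILC3 genes lower in the Nr4a1 knockout, on its single array. All 15 measured T cell markers were higher, with a median difference of 8.84, against 0.49 between the wild types. Cd8b1, a CD8 co-receptor chain, was at 18.73 against 5.0, a difference of 13.73. Cd8a was higher by 11.13, Cd3g, of the T cell receptor complex, by 10.29 and Themis, which acts in thymocyte selection, by 12.48. Dntt, the terminal transferase of antigen receptor rearrangement, was higher by 12.24 and Lef1, a transcription factor of early T cells, by 11.95. The genes of the sort markers differed too. Ptprc (CD45) was at 15.93 against 12.54 and Thy1 (CD90) at 16.00 against 12.36, both named after their values were seen. Every gene group of this comparison was measured in the same array as these T cell genes.

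Of 30 ILC3 surface receptors 21 were lower and 5 higher in the Nr4a1 knockout, with a median of -3.02 beside the T cell median of 8.84. Kit, the stem cell factor receptor, was at 5.48 against 18.36, a difference of -12.88. Ncr1, which encodes NKp46, was lower by -12.05, the IL-23 receptor gene Il23r by -10.70, Cxcr6 by -9.85 and Il7r by -2.98. Of 20 ILC3 transcription factors 14 were lower and 3 higher, with a median of -2.71. Rora was lower by -11.79, Nfil3 by -9.11 and Maf by -6.91, and Bcl11b, which the T cell list also holds, was higher by 8.14. Of 16 cytokines and effectors 8 were lower and 1 higher, with a median of -1.18, and of -0.76 against the other wild type. Csf2 was lower by -12.34. Il22 stood at the ceiling in both arrays, so no difference can be given for it, and Il17a, near the array median in both, differed by -0.26. Markers of inducer-like ILC3s had a median of -2.04, and of -2.74 against the other wild type, with Cd4, also a T cell marker, higher by 7.84. Markers of ILC3s with natural cytotoxicity receptors had a median of -4.91, and of -4.31 against the other wild type, with 12 of 15 lower and 0 higher. Klrb1b was lower by -12.14 and Il2rb by -6.16.

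The NR4A family was lower as a whole in the Nr4a1 knockout, with Nr4a2 at -7.81 and Nr4a3 at -7.36. Its median of -7.36 lay at percentile 1.16 of random triples matched on mean expression, but at 7.27, inside the central 95%, of triples matched on wild-type level. The family includes Nr4a1, the targeted gene, so only Nr4a2 and Nr4a3 carry information beyond the deletion here. Of 33 other immediate-early genes 27 were lower and 3 higher, with a median of -4.91, again on the array with the T cell genes. Fosb was lower by -11.18, but by -8.81 against the other wild type, Rgs1 by -10.10 and Gadd45b by -9.60. Heat shock genes had a median of -1.57, with Hspa1b lower by -10.05. The wild types differed on that list by a median of 1.02, and against the other wild type its median was -0.52 and Hspa1b was lower by -5.27. Of 31 apoptosis regulators 13 were lower and 8 higher, with a median of -0.29. Cdkn1a, an inhibitor of cell division, was lower by -11.74 and Bcl2a1d by -7.43, while Bcl2 was at 13.36 against 13.16. The Bcl2a1 genes are near-identical copies.

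Notch2 was lower by -2.91 in the Nr4a1 knockout, at 7.46 against 10.37, and Notch1 was at 5.11 against 3.69. On this array, where T cell genes were higher, the ILC3 surface receptors had a median of -3.02. An effect of Nr4a1 loss on Notch2 therefore cannot be told apart from the content of the sample. Of 9 Notch receptors and ligands 4 were lower and 1 higher, with a median of -0.24, but of -0.91 against the other wild type, and the wild types differed by -0.48. Of 28 Notch components and targets 10 were lower and 8 higher, with a median of 0.05, or 0.15 against the other wild type. Hey1 was lower by -7.93, Rbpj, the DNA-binding partner of Notch, by -5.00 and Myc by -4.11, the last by -1.30 against the other wild type. Alkbh5, at -0.43, did not reach the 2-fold size. The m6A genes had a median of 0.11, and of 0.28 against the other wild type, with Mettl14, of the writer complex, higher by 2.13 and the reader Ythdc1 lower by -2.17.

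Genes of cell division were higher in the Nr4a1 knockout, on the array where all 15 T cell markers were higher. Whether ILC3s without Nr4a1 divide more cannot be read from these values, because genotype and sample content are confounded. Of 39 cell cycle genes 34 were higher and 1 lower, with a median of 3.35, against 0.09 between the wild types. Ccnb2, a mitotic cyclin, was higher by 7.87, Plk1 by 7.74 and Mki67 by 6.58. Of 55 replication-dependent histone genes 49 were higher and 2 lower, with a median of 4.86, and H2ac15 was higher by 10.28. Oxidative phosphorylation genes were higher in 48 of 82 and lower in 1, with a median of 1.15. Glycolysis genes had a median of 1.25, with Pgk1 higher by 4.33 and Hk2 lower by -5.43. Fatty acid oxidation genes had a median of -0.10, interferon-stimulated genes of 0.23, or 0.03 against the other wild type, and ribosomal protein genes of 0.00.

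Markers of most other cell types were lower in the Nr4a1 knockout, on the array where T cell markers were higher. Of 32 intestinal epithelial markers 29 were lower and 0 higher, with a median of -3.05. Defa21, a Paneth cell defensin, was at 3.43 against 16.34, and Defa22 was lower by -12.01. Against the other wild type Defa21 was lower by -8.64 and Defa22 by -8.16. Those markers also differed between the wild types, with 24 of 32 higher in the Nr4a1 wild type and a median of 1.54, and against the other wild type their median was -0.87. Macrophage markers had a median of -1.87, plasma cell markers of -2.39, stromal and endothelial markers of -2.55 and MHC class II genes of -1.87. Against the other wild type the macrophage median was -1.06, the stromal and endothelial median -3.62 and that of MHC class II genes -0.40. The wild types differed on MHC class II genes by 1.26. NK cell and ILC1 markers had a median of -1.94 and ILC2 markers of -1.62. Chemokines and their receptors had a median of -2.12, with Cxcl2 lower by -9.59. Hepatocyte and pancreas markers had a median of -2.97, with Amy2a5 lower by -9.49, and a median of -4.72 against the other wild type. B cell markers had a median of -0.57, and of -0.34 against the other wild type, and neutrophil markers of -0.50. Ly6c2, on the macrophage list, was higher by 5.58, and Ccr9, on the dendritic cell list, by 7.68.

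By the rule of size 3574 genes were higher and 2327 lower in the Nr4a1 knockout, 52.7% of the 11197 genes past the filter. Against both wild types, 3042 were higher and 1701 lower. The 10 highest also held Itm2a at 12.58, Aqp11 at 12.45 and Sh2d1a at 10.32. The 10 lowest also held Ptgs2 at -14.12, Lilrb4a at -13.00, Ramp3 at -12.86, Gem at -12.75, Dgat1 at -12.30 and Plekhg1 at -12.16. With both wild types treated as 1 group, limma called 1428 genes higher and 752 lower at its adjusted p. That fit assumes that the lone knockout array varies like the wild types, and since the genotype has 1 array, no count without that array can be given.

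**Figure D2:**
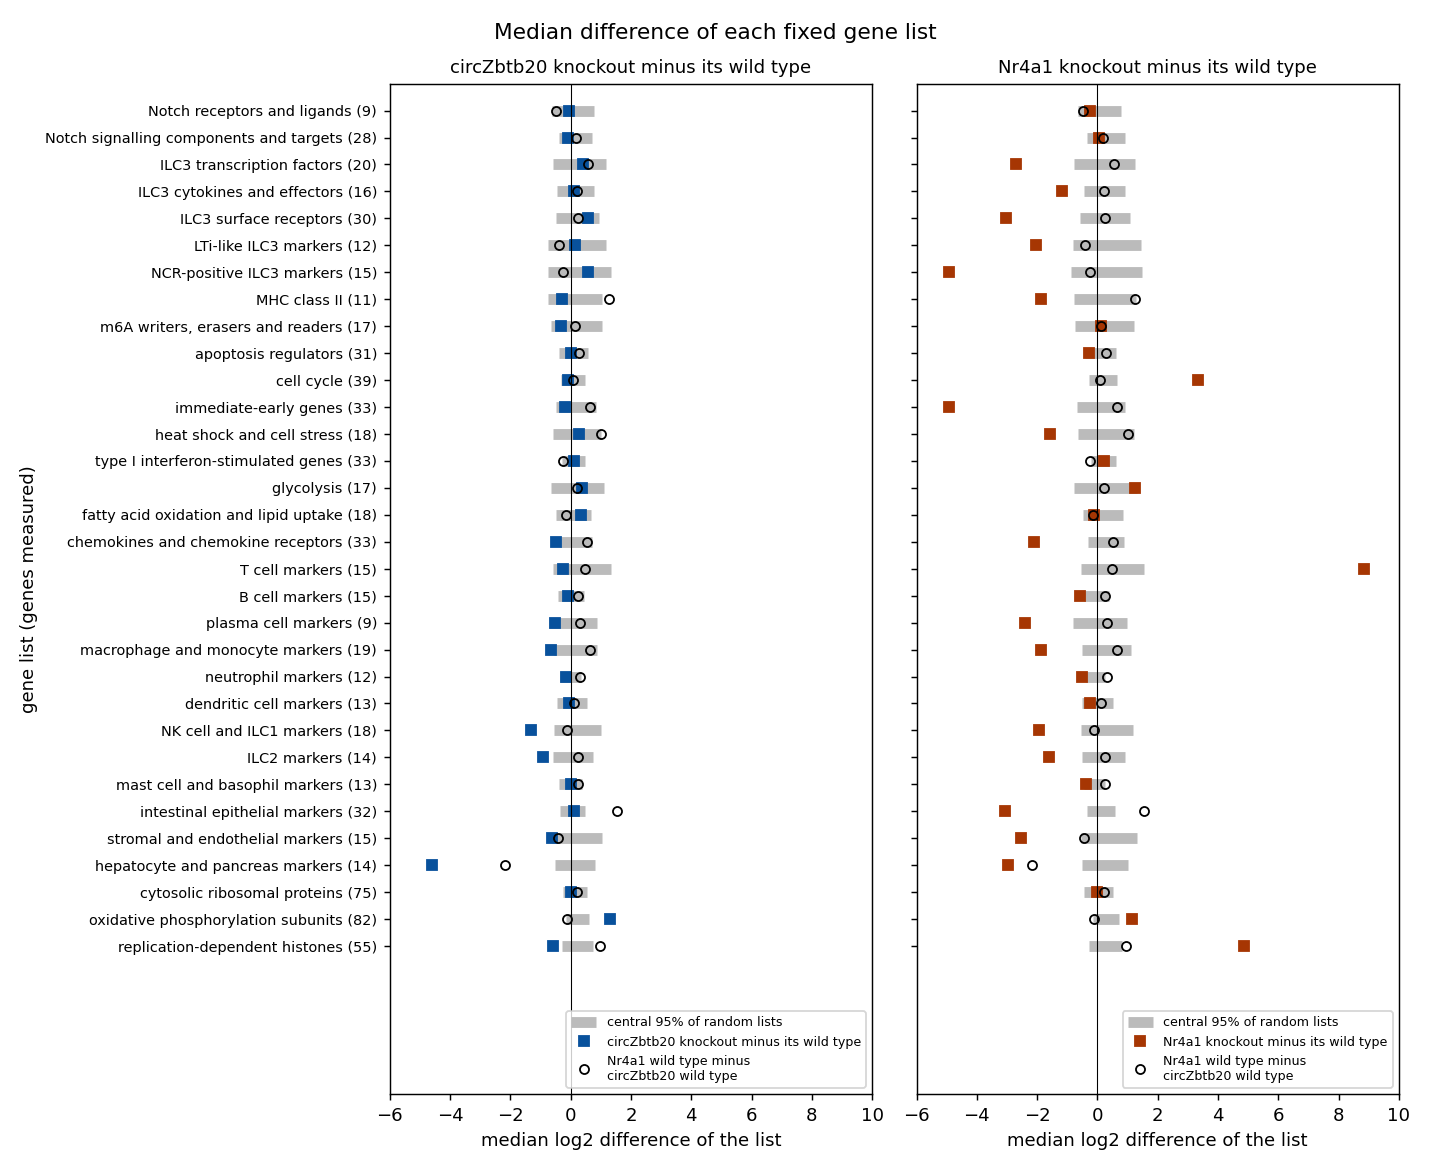
Median log2 difference (horizontal axis) of each fixed gene list with 9 or more measured genes (vertical axis, number measured in brackets), for the circZbtb20 knockout on the left and the Nr4a1 knockout on the right as squares, with the difference between the wild types as circles and the central 95% of matched random lists as grey bars. T cell markers lie at -0.26 on the left and 8.84 on the right, and oxidative phosphorylation subunits at 1.29 and 1.15.

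The background between the wild types was smaller than either knockout difference by count and by correlation. Across all 22205 rows the wild types correlated at Pearson r = 0.974, against 0.902 for the circZbtb20 pair and 0.839 for the Nr4a1 pair. These are correlations across rows, which are not independent replicates. Between the wild types 907 genes were higher in the Nr4a1 wild type and 724 lower. Immediate-early genes had a median of 0.64 and heat shock genes of 1.02 in the direction of the Nr4a1 wild type. MHC class II genes had a median of 1.26 and histone genes of 0.96 in that direction. The 3 measured sex-linked genes were all higher in the Nr4a1 wild type, with a median of 5.64. The Y-linked genes Uty, at 2.65, and Kdm5d, at 2.89, were under the array median in the circZbtb20 wild type alone, and Eif2s3y was under it there, at 3.04, and in the circZbtb20 knockout, at 3.79. Sex of the mice, mouse line, litter, day and array cannot be told apart in these differences.

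The last comparison set the knockouts side by side, each against its own wild type, so that no array was shared. Genes lower in both included pancreatic enzymes, a cytokine, a chemokine and a chemokine receptor. Ccl3 was lower by -7.62 in the circZbtb20 knockout and by -9.51 in the Nr4a1 knockout. Il5, the type 2 cytokine, was lower by -8.16 and -6.19, Ccr8 by -6.93 and -5.67 (-3.35 in the Nr4a1 knockout against the other wild type) and the metallothionein Mt1 by -6.25 and -7.77. Ifrd1 was lower by -6.85 and -9.34 and Hs3st1 by -6.08 and -9.88. Against the other wild type Hs3st1 was lower by -8.13 and -7.83, and Ccr8 in the circZbtb20 knockout by -9.25. Amy2a2 was lower by -9.84 and -11.57, Amy2a4 by -9.62 and -10.80, and Ctrb1 by -10.89 and -9.27.

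Among 10090 genes past the filter in both comparisons, 635 were lower in both knockouts, where independent lists of those sizes would share 428.1. There were 1024 genes higher in both, against 861.1. Genes higher in the circZbtb20 knockout and lower in the Nr4a1 knockout numbered 571, against 583.8, and the opposite pairing gave 577, against 631.5. These expected numbers are not matched on expression. A gene called lower must lie above background in its wild type, and the wild types correlated at r = 0.974. An excess in the same direction therefore does not by itself show a shared response. Across 12229 genes the differences correlated at Pearson r = 0.094 and Spearman rho = 0.106, and genes are not independent replicates. After cyclic loess normalization, 634 genes were higher in both, with no expected number made for that setting. Several genes stood apart between the knockouts. Kit was higher by 1.60 in the circZbtb20 knockout and lower by -12.88 in the Nr4a1 knockout, and Ifng was higher by 9.88 and lower by -5.41. Against the other wild type Ifng was higher by 8.09 and lower by -3.62.

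**Figure D3:**
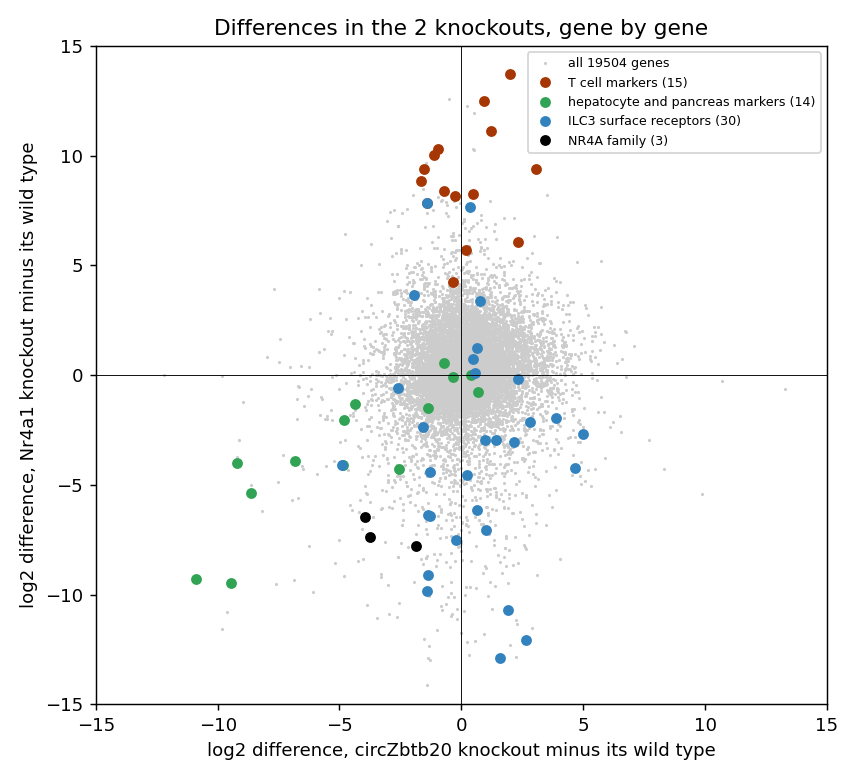
Log2 difference of each of 19504 genes in the circZbtb20 knockout (horizontal axis) and in the Nr4a1 knockout (vertical axis), each against its own wild type, with 4 fixed gene lists in colour. The T cell markers lie high on the vertical axis, up to 13.73, most of the hepatocyte and pancreas genes lie to the lower left, down to -10.89 on the horizontal axis, and the NR4A family lies between -7.81 and -6.48 on the vertical axis.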

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

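Tests chosen only after the result was seen were the reading of the number of arrays, both immediate-early tests and the reading of percentile 2.41 as open. The other tests of this part were written before their results were seen, though after the patterns themselves.

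In the Nr4a1 knockout array T-lineage genes were higher and ILC3 genes lower. The T cell marker median stayed at 8.31 after cyclic loess normalization, which removes only offsets that vary smoothly with signal level. This argues against such an offset between the arrays, and not against every fault of processing. RNA of T-lineage cells in place of ILC3 RNA is a candidate explanation, as a second list of T cell genes, sharing none with the first, had a median of 3.10, with 8 of 12 higher and 1, Txk, lower. Of that list 11 genes were at or above the array medians in both wild types, while the first list had a median level of 15.6 in the knockout, with Cd3e at 18.92. Of 15 ILC3 surface receptors abundant in the wild types, 12 were lower, with a median of -6.16, against 0.77 in the circZbtb20 knockout. Among the rows of the Nr4a1 knockout array Ncr1 lay at percentile 10.1, Il23r at 55.9 and Kit at 63.8. Il7r, at 97.2, and Cd69, at 98.7, stayed high. These receptors were picked for their abundance, so they describe the array and test nothing. A lineage-negative sort would be meant to remove T cells. Il22, a cytokine that ILC3s make, was at the ceiling on both Nr4a1 arrays, while Kit, Ncr1 and Il23r fell. A full replacement of ILC3 RNA would not by itself account for that Il22 level. Whether the row measures Il22 alone was not tested, and the ceiling hides any fall, so this 1 gene does not settle the question. An effect of the loss of Nr4a1 on ILC3s cannot be told apart from the content of the sample, because the genotype has 1 array.

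The NR4A family was lower in both knockout arrays. In the Nr4a1 knockout the family includes the targeted gene itself, so only Nr4a2 and Nr4a3 carry further information there. For the circZbtb20 knockout the test of a general drop of immediate-early genes turned on the reference, with medians of -0.18 (spread 1.57) beside -3.73 or lower for the NR4A family against its own wild type, but -1.27 (spread 1.35) beside -2.59 against the other, so it decides nothing. The test of a drop of abundant genes gave percentile 2.41 among random triples matched on wild-type level, but Nr4a1 and Nr4a3 were at the ceiling in the wild type, so both explanations stay open. For the Nr4a1 knockout a drop of abundant genes could account for the values, at percentile 7.27, while the immediate-early median of -4.91 (spread 3.60), and -3.40 (spread 3.84) against the other wild type, beside NR4A medians of -7.36 and -7.39 or lower, decides nothing. An effect of either genotype stays open and untested.

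Pancreatic enzyme genes were lower in both knockout arrays. The higher of the list's medians stayed at -3.45 after cyclic loess normalization, which again argues only against a smooth offset between the arrays. Acinar cell RNA in the wild-type preparations is a candidate source, which a sort for CD90-high cells would be meant to remove. A second acinar list had a median of -1.37 in the circZbtb20 knockout and -0.95 in the Nr4a1 knockout, and the latter missed the bound of -1 set beforehand, so the explanation stays open. Rnase1 was at 9.57 and Reg1 at 8.65 in the circZbtb20 wild type, but at 4.07, under the array median, and 5.32 in the Nr4a1 wild type. Of the 17 second-list genes, 9 were at or above the array medians in both wild types. The others were under the median in a wild type, where a fall is poorly measured. The missed bound therefore does not argue against acinar cell RNA. No biological explanation was tested.

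Several lists lay on opposite sides in the knockout comparisons when each was set against its own wild type, and the difference between the comparisons was not tested. Sex-linked genes had a median of 4.70 in the circZbtb20 knockout and -3.12 in the Nr4a1 knockout, but of 1.02 and 2.80 against the other wild type, with Uty at 2.65, 10.98, 9.96 and 5.69 in the circZbtb20 wild type, its knockout, the Nr4a1 wild type and its knockout. Replication-dependent histone genes had medians of -0.60, which was -1.32 against the other wild type, and 4.86, which was 6.06. The 1425 olfactory and vomeronasal receptor genes, which these cells are not thought to use, had medians of 0.07 and -0.12, and of 0.01 and -0.04 against the other wild type. Among rows without a gene symbol, which the gene counts and lists of the report left out, 50.1% of those past the filter differed 2-fold in the circZbtb20 comparison and 46.7% in the Nr4a1 comparison, against 18.8% between the wild types.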

How the results depend on the processing

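Counts without genes at the ceiling and over all rows were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each genotype has 1 array. Of the counts and the correlation, 103 values under alternatives stayed within 1.5 times (0.05 for the correlation) of the reported ones and 27 did not. At 3-fold the circZbtb20 knockout had 1864 genes higher and 1190 lower, and 1435 and 836 against both wild types. The Nr4a1 knockout had 2292 and 1503, and 1898 and 1125 against both, with 412 genes higher and 281 lower in both knockouts. At 1.5-fold, 2440 were lower in the circZbtb20 knockout against both wild types, with 1795 higher and 1095 lower in both knockouts. These follow from the size asked for. With the filter at the 75th percentile, which passes fewer genes, 1333 were lower in the circZbtb20 knockout, 1443 in the Nr4a1 knockout and 411 in both. Cyclic loess gave 634 genes higher in both, and the cause was not tested. With limma, which asks for an adjusted p, 0 were higher and 0 lower in the circZbtb20 knockout (smallest adjusted p 0.0511, 4681 at an unadjusted p under 0.05) and 1428 higher and 752 lower in the Nr4a1 knockout. A list median moved when it shifted by over 1 SD of its matched random lists, and a gene by over 1 SD of the wild-type difference among genes of like level. For list medians, 297 values kept to the reported ones, 72 moved and 1 reversed. For named genes these numbers were 1244, 210 and 6. Every reversal came with the other wild type as reference, because the wild types differed: the sex-linked median in the Nr4a1 knockout was 2.8, Eif2s3y 2.52 and Uty 3.04, and in the circZbtb20 knockout H2-Eb1 was -0.34, H2-Ob 0.17, Lgals4 -0.94 and Muc2 -1.45. Nr4a1 differed by -2.13 in the circZbtb20 knockout and -8.30 in the Nr4a1 knockout against the other wild type, and by -3.04 and -7.39 against the mean of both. Signal near background limits genes under the array medians, and the ceiling limits the most abundant.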

Other observations

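Further lists described the content of the samples. In the circZbtb20 knockout T cell markers had a median of -0.26, B cell markers of -0.10, plasma cell markers of -0.51, with Jchain lower by -4.83, and stromal and endothelial markers of -0.62, with Col3a1 lower by -3.34. Neutrophil markers had a median of -0.15, dendritic cell markers of -0.07, mast cell and basophil markers of 0.00 and erythroid markers of 0.01. Intestinal epithelial markers had a median of 0.11, with 11 of 32 higher and 8 lower, and Tff3, a goblet cell peptide, was higher by 5.20, but by only 1.49 against the other wild type. Against it the epithelial median was -1.57, the neutrophil median -0.45, the mast cell median -0.29, the dendritic cell median 0.01 and the erythroid median -0.12. The B cell median was -0.25, the plasma cell median -0.82, the stromal median -0.40, Jchain was lower by -7.79, Col3a1 by -1.36 and H4c14 was higher by 2.70. Among histone genes 22 of 55 were lower and 9 higher, with H4c14 higher by 4.11 and H3c6 lower by -2.91. The 6 microRNA genes had medians of -0.27 in the circZbtb20 knockout and -0.21 in the Nr4a1 knockout. In the Nr4a1 knockout dendritic cell markers had a median of -0.25, mast cell markers of -0.39 and erythroid markers of -0.01, the last of -0.23 against the other wild type. Immunoglobulin segments and small nucleolar RNAs each had 1 measured gene, and T cell receptor segments had 0, so no median was given.

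Genes of developing thymocytes, listed after values were seen, were higher in the Nr4a1 knockout array in 15 of 15 cases, with a median of 7.27 against 0.24 in the circZbtb20 knockout and 0.18 between the wild types. Rag2, of antigen receptor rearrangement, was at 10.50 against 4.04, Ptcra, the pre-T cell receptor alpha chain, at 7.51 against 3.70 and Satb1 at 19.49 against 15.28. The list shares 3 genes with the T cell list, and 5 of its genes were at or above the array medians in both wild types.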
